A study of Mus musculus with 9 samples.

How the data were processed

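Poly(A) RNA from HL-1 cells was sequenced as 9 libraries, 3 per group, on the Ion Proton system after capture with a magnetic bead kit and library construction with an Ion Total RNA-Seq kit, per the labels' protocols. The groups were 0.1% DMSO vehicle, 5 µM ivermectin and 10 µM importazole, all for 24 h. Group and replicate number were taken from the labels. The deposited files hold a gene symbol and an FPKM value (fragments scaled to transcript length and to all mapped fragments), per the file headers. The submitters' processing notes name STAR, Bowtie2, Bowtie and Cufflinks, with no versions or roles, and the builds mm10 and GRCm38. The annotation, the use of strand and any filter are not given in the sources used here. FPKM removes differences in read number and transcript length but is relative to all mapped fragments, so an abundant transcript that is missing from a library raises the values of the others. The values did not step in whole reads, so reads and depth could not be recovered, and no counting interval is given.

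Each file held 25230 lines for 25175 symbols. The values of 48 symbols listed more than once were summed, and 20 of these symbols were among the genes tested. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 11337 genes, and values were analysed as log2(FPKM + 1) with no further scaling between libraries. Locations, transcript length and GC content came from GENCODE M21 on GRCm38, in which 24172 symbols matched 1 gene, 49 matched more than 1 and 954 matched none. A linear model with group as the only term was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with the intensity trend and robust empirical Bayes moderation. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed in each of 3 comparisons: ivermectin with vehicle, importazole with vehicle, and ivermectin with importazole. All p-values are two-sided.

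The groups, comparisons, test, filter, 45 gene lists and rule for named genes were fixed before the data were examined. Lists with at least 3 tested members, 39 of the 45, were tested against all other genes with limma's camera and a preset correlation between genes of 0.01, with adjustment over the 39 lists of a comparison. Calls were repeated with the correlation estimated from the data. For lists described as higher or lower in the report, the number of members past the threshold is given over all genes tested and when adjusted over the list alone. Tested members shared between lists were few, with no gene in common between the cholesterol synthesis, glycolysis, hypoxia and mitochondrial lists.

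The genes named were, in each comparison, the 8 largest increases and 8 largest decreases among genes past the threshold whose 3 libraries of one group all lay above the 3 of the other and whose mean over the 9 libraries was at least 5 FPKM, leaving out predicted genes, small RNAs, ribosomal protein pseudogenes and unnamed loci. In each list described, up to 4 members with the smallest p were eligible, and a member of each direction where calls went both ways. A fixed set of 7 nuclear import genes and 8 HL-1 identity genes is reported whatever its result, except that 1 identity gene and 1 of the largest decreases are not reported here. Other genes named were chosen after their values were seen: Ddr2, Col1a1, Kdr, Eng, Cd68 and Acta2 among the markers, and those said to be so in the closing section.

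Both comparisons with vehicle share 3 libraries, so their similarity was set beside 100 simulations of unchanged groups. The procedure was tested on simulated data for all 11337 genes. It recovered 56.7%, 94.0% and 100% of simulated log2 changes of 0.5, 1 and 2 for ivermectin with vehicle, 61.2%, 91.0% and 100% for importazole with vehicle, and 62.7%, 91.0% and 98.5% for the direct comparison. False calls made up 6.70%, 7.69% and 6.145% of calls in the same order. A list shifted by 0.4 was called in each comparison, with 0 other lists called by camera in these simulated data. The simulated genes were drawn independently, so this cannot show how often lists of correlated genes are falsely called. The correlation estimated from the real data was up to 0.603, for the mitochondrial list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

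Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, quantile normalization, fits to the 6 libraries compared, the replicate number as a block, stricter thresholds, another set test, an estimated correlation and leaving out each library. Added after the data were seen were median-of-ratios scaling, removal of the trend with GC content and transcript length, and leaving out both libraries that list Yam1 at 0. Leaving Yam1 itself out of the comparison of both compounds' effects was also added then. Alternatives planned for read counts were not run because the files hold FPKM, and the test planned for FPKM was used.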

Results

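RNA sequencing was used to measure transcript levels in HL-1 cells, an immortalised line of mouse atrial cardiomyocytes that keeps features of differentiated heart muscle. The cells were exposed for 24 h to vehicle (0.1% DMSO), to 5 µM ivermectin or to 10 µM importazole, with 3 libraries in each of the 3 groups. Ivermectin is an antiparasitic drug that is also used in the laboratory as an inhibitor of importin α/β, the receptor pair that carries many proteins into the nucleus. Importazole is a small-molecule inhibitor of importin-β. The compounds are not structural relatives and were given at different doses, so their effects were compared at these doses only. The labels give no DMSO content for the compound groups and do not say that the libraries came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

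The deposited values were FPKM, from which read numbers could not be recovered, so the depth of each library is unknown. Summed FPKM ranged from 365300 in vehicle 2 to 416700 in vehicle 1, and 11055 to 11200 genes per library reached 1 FPKM. Across the 11337 genes tested, Pearson correlations of log2(FPKM + 1) were 0.9841 to 0.9918 within groups and 0.9797 to 0.9902 between groups. Genes are not independent replicates. A single transcript, Yam1, was listed at 0 in vehicle 2 and ivermectin 3 and made up 5.86% to 10.43% of summed FPKM in the other 7 libraries. The median log2(FPKM + 1) was 3.423 in vehicle 2 and 3.504 in ivermectin 3. Neither lay above the other 7 libraries, at 3.444 to 3.529. All fold changes below are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The use of strand in the authors' quantification is not given in the sources used here, so values of genes whose exons overlap a tested gene on the opposite strand are uncertain. Among genes named below this holds for Aldh1l2, Psph, Atf5, Cyp51, Fdft1, Acss2, Srr and Ddr2.

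The comparison of ivermectin with vehicle asked which transcripts differed after the importin α/β inhibitor. Genes of the amino acid response, which the transcription factor ATF4 switches on when amino acids run short, rose, while hypoxia-inducible genes and genes of cholesterol synthesis fell. Glycolytic genes also fell, a list call that did not hold with an estimated correlation between genes (adjusted p = 0.0627 with an estimated correlation). Trib3, a pseudokinase gene induced by ATF4 (GRCm38 chromosome 2, 152337422 to 152344032, minus strand), rose from 12.3 ± 0.692 to 51.6 ± 1.05 FPKM (mean ± SD, n = 3). Its log2 change was 1.99 (limma adjusted p = 1.03e-07). Bnip3, a hypoxia-inducible receptor for the removal of mitochondria (chromosome 7, 138890836 to 138909519, minus strand), fell from 41.7 ± 1.497 to 9.93 ± 0.546 FPKM. Its log2 change was -1.97 (limma adjusted p = 1.15e-07). In all, 489 of the 11337 genes passed the test, 203 of them higher and 286 lower. Of these, 40 changed by at least 1 log2 unit, 24 of them upward and 16 downward.

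Among the 28 tested genes of the amino acid response, 23 rose, 1 fell and 4 did not pass (24 and 1 when adjusted over the list alone). The median log2 change was 0.73 (camera adjusted p = 2e-30, or 0.0236 with an estimated correlation). Besides Trib3, Aldh1l2, a mitochondrial folate enzyme, rose from 9.29 ± 0.347 to 26.1 ± 0.371 FPKM. Mthfd2, another enzyme of mitochondrial folate metabolism, rose from 78.0 ± 3.10 to 165 ± 11.1 FPKM. Asns, which makes asparagine, went from 53.3 ± 2.48 to 130 ± 17.3 FPKM, and Psph, which completes serine synthesis, from 29.0 ± 2.34 to 69.4 ± 7.58 FPKM. Fgf21, a secreted metabolic hormone, had a log2 change of 1.87 from a vehicle level of 0.548 ± 0.0998 FPKM. The member that fell was Ddit4, an inhibitor of mTORC1 signalling that hypoxia also induces, from 13.5 ± 0.595 to 8.74 ± 1.27 FPKM (limma adjusted p = 0.0106). The other genes with the largest increases were Nupr1 (log2 change 1.56), Cox6a2 (1.37), a muscle subunit of cytochrome c oxidase, Gadd45a (1.32), a stress-inducible growth arrest gene, and the glycine transporter Slc6a9 (1.25).

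Of the 17 tested hypoxia-inducible genes outside glycolysis, 13 fell, 1 rose and 3 did not pass (14 and 1 when adjusted over the list alone). Their median log2 change was -0.86 (camera adjusted p = 4.72e-19, or 0.00522 with an estimated correlation). Egln3 and Egln1, oxygen-sensing prolyl hydroxylases, fell from 22.0 ± 0.406 to 5.64 ± 0.416 FPKM and from 61.1 ± 2.96 to 33.2 ± 0.0939 FPKM. The lactate transporter Slc16a3 fell from 117 ± 10.7 to 37.8 ± 3.45 FPKM. The vasodilator peptide gene Adm and Pdk1, a kinase that restrains pyruvate oxidation, had log2 changes of -1.06 and -1.03. Pfkfb3, an activator of glycolytic flux, was the member that rose, from 4.80 ± 0.109 to 6.90 ± 0.352 FPKM. Of the 16 glycolysis genes 13 fell and 3 did not pass (14 when adjusted over the list alone). Glycolysis genes had a median log2 change of -0.46 (camera adjusted p = 3.52e-16; adjusted p = 0.0627 with an estimated correlation). The glucose transporter Slc2a1 fell from 50.9 ± 0.705 to 25.2 ± 0.878 FPKM, Pfkl from 47.2 ± 3.54 to 22.0 ± 3.93 FPKM and Ldha, which makes lactate, from 1882 ± 4.09 to 1254 ± 46.2 FPKM.

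Of the 23 tested genes of cholesterol synthesis and uptake, 16 fell and 7 did not pass (20 when adjusted over the list alone). Their median log2 change was -0.43 (camera adjusted p = 3.29e-19, or 0.0236 with an estimated correlation). Cyp51, a sterol demethylase, fell from 65.4 ± 2.12 to 40.1 ± 4.55 FPKM. Hmgcs1, which feeds the mevalonate pathway, fell from 24.5 ± 1.86 to 16.9 ± 0.365 FPKM. Large decreases outside these lists were those of the selenium-binding protein gene Selenbp1 (log2 change -1.33), which is uncertain because reads can be shared with its near-identical copy Selenbp2, and of the transferrin receptor Tfrc (-1.23).

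In the sarcomere list, 12 of 27 genes fell and 15 did not pass (19 lower and 1 higher when adjusted over the list alone). The list had a median log2 change of -0.23 (camera adjusted p = 1.38e-09; adjusted p = 0.127 with an estimated correlation). Mybpc3, a regulator of myosin, fell from 167 ± 8.18 to 114 ± 4.79 FPKM, and Xirp1, an actin-binding protein gene, from 37.9 ± 1.55 to 25.0 ± 1.16 FPKM. Of 21 calcium-handling genes 4 fell and 17 did not pass (6 when adjusted over the list alone). Their median log2 change was -0.16 (camera adjusted p = 1.16e-04; adjusted p = 0.0517 with an estimated correlation). The sodium-calcium exchanger Slc8a1 fell from 68.7 ± 2.31 to 54.7 ± 1.66 FPKM. Of 18 cardiac transcription factors 3 fell and 15 did not pass (7 when adjusted over the list alone). These factors had a median log2 change of -0.20 (camera adjusted p = 3.52e-05; adjusted p = 0.0911 with an estimated correlation). Srf, a regulator of muscle genes, went from 29.4 ± 1.26 to 21.5 ± 1.46 FPKM. Ribosomal protein genes were higher as a list, with a median log2 change of 0.19 (camera adjusted p = 2.63e-10; adjusted p = 0.352 with an estimated correlation). Of the 77, 1 passed limma's test and 0 when adjusted over the list alone, with 39 higher at an unadjusted p under 0.05, and many have pseudogene copies that could share reads. Their mean lay 0.0593, 0.148 and 0.337 above the vehicle mean in ivermectin 1, 2 and 3, and 0.0826 above it in vehicle 1, and the median log2 change was 0.114 without ivermectin 3. The list did not pass the other set test, fry (adjusted p = 0.0781). The sarcomere, calcium-handling and cardiac transcription factor lists passed fry (adjusted p = 0.00255, 8.52e-04 and 0.00467).

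In all, 21 of the 39 lists passed with a preset correlation, 7 upward and 14 downward, and 3 held with an estimated one: the amino acid response, hypoxia-inducible genes and cholesterol synthesis. The number of changed genes was 262 without vehicle 1, 243 without vehicle 2, 304 without ivermectin 1 and 311 without ivermectin 3. It was 190 without both libraries that list Yam1 at 0, where the calls of Ddit4, Pfkfb3 and Srf also ended.

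**Figure D1:**
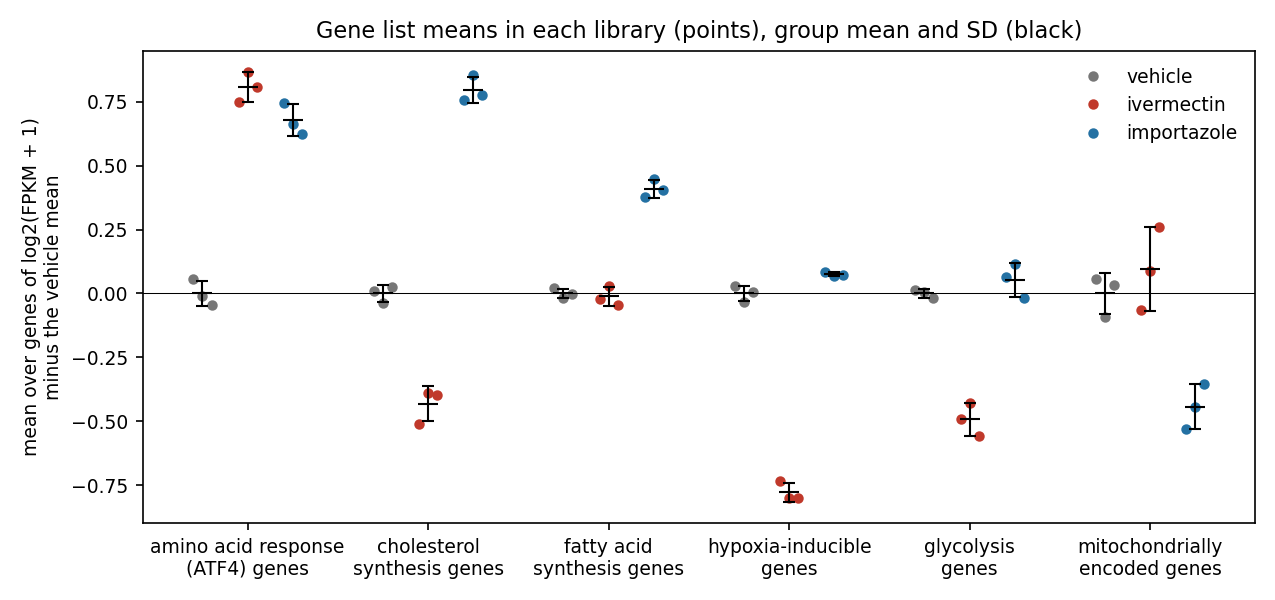
Mean over the genes of 6 lists of log2(FPKM + 1) minus the vehicle mean, for each library (points, 3 per group), with the group mean and SD in black. The cholesterol synthesis list lay at -0.510 to -0.388 in the ivermectin libraries and at 0.756 to 0.854 in the importazole libraries, while the amino acid response list was above vehicle in all 6.

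The comparison of importazole with vehicle asked the same of the importin-β inhibitor. Genes of cholesterol synthesis, fatty acid synthesis and the amino acid response rose. Of 13 transcripts encoded in the mitochondrial genome 7 fell, a list call that did not hold with an estimated correlation (adjusted p = 0.129 with an estimated correlation). Fdps, which makes the isoprenoid precursor of sterols (chromosome 3, 89093588 to 89101959, minus strand), rose from 68.2 ± 1.73 to 179 ± 4.61 FPKM. Its log2 change was 1.38 (limma adjusted p = 2.12e-06). The mitochondrial gene mt-Cytb (chromosome M, 14145 to 15288, plus strand), a subunit of respiratory complex III, fell from 936 ± 96.5 to 574 ± 60.9 FPKM. Its log2 change was -0.71 (limma adjusted p = 0.00255). In all, 256 of 11337 genes passed, 192 higher and 64 lower, and the 18 that changed by at least 1 log2 unit were higher.

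In the cholesterol synthesis list 21 of 23 genes rose and 2 did not pass (22 when adjusted over the list alone). The median log2 change was 0.78 (camera adjusted p = 1.89e-35, or 0.00664 with an estimated correlation). Insig1, a sterol sensor, rose from 53.02 ± 2.25 to 117 ± 3.64 FPKM, Idi1, an isomerase of isoprenoid precursors, from 17.8 ± 0.413 to 44.0 ± 1.86 FPKM and Cyp51 from 65.4 ± 2.12 to 155 ± 9.78 FPKM. The log2 change was 1.19 for the sterol oxidase gene Msmo1 and 1.03 for Fdft1, the enzyme that makes squalene. Of the 15 fatty acid synthesis genes 8 rose and 7 did not pass (13 when adjusted over the list alone). Their median log2 change was 0.41 (camera adjusted p = 2.4e-13, or 0.00664 with an estimated correlation). Acly, which supplies cytosolic acetyl-CoA, rose from 57.5 ± 3.78 to 94.4 ± 0.530 FPKM, the desaturase Scd2 from 273 ± 2.51 to 425 ± 26.3 FPKM and Fads1, another desaturase, from 95.0 ± 1.28 to 137 ± 2.15 FPKM.

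In the amino acid response list 22 of 28 genes rose and 6 did not pass (24 when adjusted over the list alone). The median log2 change was 0.59 (camera adjusted p = 1.44e-31, or 0.015 with an estimated correlation). Trib3 reached 39.8 ± 1.97 FPKM (log2 change 1.62), Aldh1l2 24.1 ± 1.36 FPKM (1.29) and Atf5, a transcription factor of the same response, 48.5 ± 2.14 FPKM from 21.2 ± 2.60 (1.16). Phgdh, which opens serine synthesis, rose from 95.6 ± 3.60 to 172 ± 0.365 FPKM, and Atf4 from 79.7 ± 6.26 to 152 ± 8.81 FPKM. Cox6a2 had a log2 change of 1.17.

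Of 13 tested mitochondrially encoded transcripts 7 fell and 6 did not pass (10 when adjusted over the list alone). They had a median log2 change of -0.45 (camera adjusted p = 1.07e-14; adjusted p = 0.129 with an estimated correlation). Besides mt-Cytb, mt-Atp6, a subunit of ATP synthase, fell from 1109 ± 15.4 to 696 ± 36.6 FPKM. The call of mt-Atp8 (log2 change -0.69, limma adjusted p = 0.032) ended when any of vehicle 1, 2 or 3, ivermectin 2 or importazole 1, 2 or 3 was left out, with adjusted p up to 0.128. The genes mt-Atp8 and mt-Atp6 share 43 annotated bases, and mitochondrial genes have nuclear copies that could share reads, so the level of each gene is uncertain.

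The largest decreases elsewhere were those of Lbh, a transcriptional cofactor gene (79.4 ± 7.80 to 40.4 ± 2.19 FPKM, log2 change -0.96), the small GTPase Rrad (-0.70) and Sh3kbp1 (-0.58), an adaptor in receptor uptake. Sema6c had a log2 change of -0.83 (limma adjusted p = 0.0154), and its call ended without vehicle 1, vehicle 3, importazole 1 or importazole 3, with adjusted p up to 0.0824. Of 21 calcium-handling genes 3 fell and 18 did not pass (5 lower and 1 higher when adjusted over the list alone). Their median log2 change was -0.09 (camera adjusted p = 3.28e-06, or 0.0229 with an estimated correlation). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell from 18.4 ± 0.778 to 12.6 ± 0.470 FPKM. In the sarcomere list 3 of 27 genes fell and 24 did not pass (11 when adjusted over the list alone). The list had a median log2 change of -0.09 (camera adjusted p = 5.9e-09; adjusted p = 0.152 with an estimated correlation). Cardiac actin Actc1 went from 684 ± 15.6 to 509 ± 15.3 FPKM. In fatty acid oxidation, 2 of 26 genes rose and 2 fell (2 and 4 when adjusted over the list alone). The log2 change was 0.47 for Acsl1, which activates fatty acids, and -0.39 for Cpt2, a mitochondrial carnitine transferase. The list passed (camera adjusted p = 0.00315, downward; adjusted p = 0.302 with an estimated correlation). Ribosomal protein genes were again higher as a list, with a median log2 change of 0.21 and 2 of 77 past the test alone, 17 when adjusted over the list alone (camera adjusted p = 8.55e-13; adjusted p = 0.381 with an estimated correlation). The hypoxia-inducible and glycolysis lists did not pass, with median log2 changes of 0.05 and 0.03 (camera adjusted p = 0.43 and 0.727). By fry the hypoxia list passed (adjusted p = 0.0399) and the glycolysis list did not (0.446). In the hypoxia list 12 of 17 log2 changes were positive and 0 genes passed limma's test.

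Of the 39 lists 19 passed, 9 upward and 10 downward, and 4 held with an estimated correlation: cholesterol synthesis, fatty acid synthesis, the amino acid response and calcium handling. The number of changed genes was 134 without vehicle 2, 142 without vehicle 3, 127, 133 and 153 without importazole 1, 2 and 3, and 161 without both libraries that list Yam1 at 0. Over all genes tested the median log2 change was 0.041. It was -0.0045 after quantile normalization and -0.0013 after median-of-ratios scaling. Lists were tested against the other genes, so the direction of a list is relative to this shift. The split of higher to lower genes, 192 to 64, depended on scaling. It was 159 to 117 after quantile normalization, 159 to 118 after median-of-ratios scaling and 208 to 158 after removal of the trend with GC content and length.

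**Figure D2:**
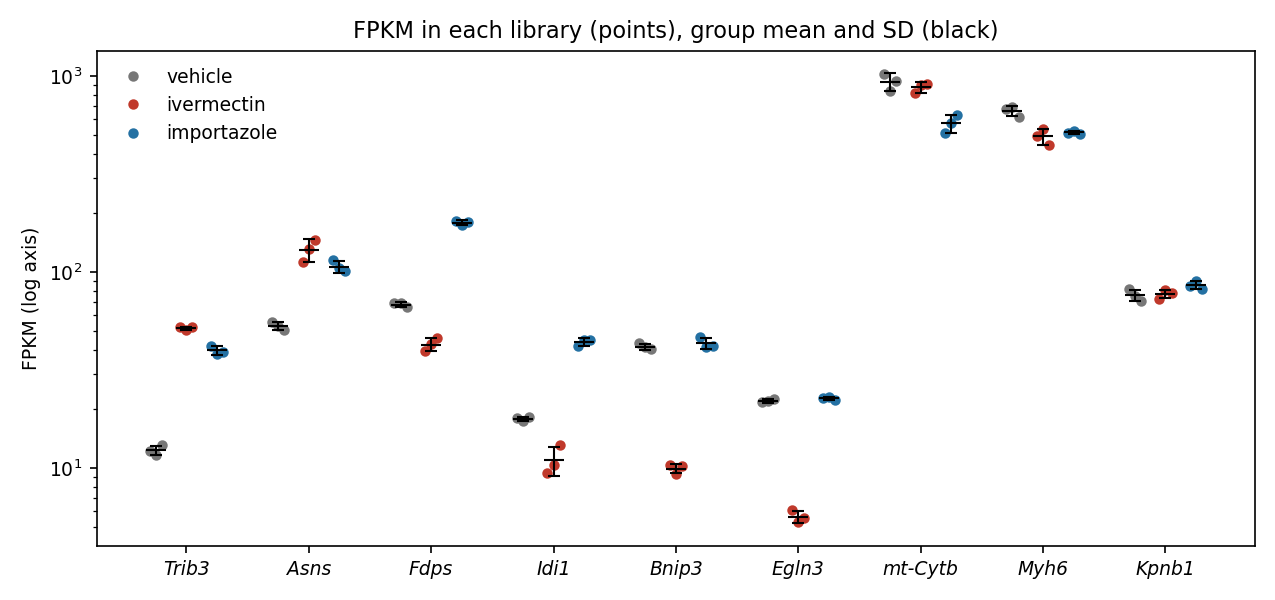
FPKM of 9 named genes in each library (points, 3 per group) on a log axis, with the group mean and SD in black. Trib3 and Asns lay above vehicle with both compounds, Fdps and Idi1 moved in opposite directions, and Bnip3 and Egln3 fell with ivermectin, to 9.93 ± 0.546 and 5.64 ± 0.416 FPKM.

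Ivermectin and importazole were compared directly to test where their effects differed. Cholesterol synthesis, fatty acid synthesis and hypoxia-inducible genes were lower with ivermectin than with importazole. Glycolytic genes were also lower and mitochondrially encoded transcripts higher, list calls that did not hold with an estimated correlation (adjusted p = 0.0857 and 0.174 with an estimated correlation). Fdps was at 42.7 ± 3.24 FPKM with ivermectin and 179 ± 4.61 FPKM with importazole, a log2 difference of -2.04 (limma adjusted p = 6.37e-08). Bnip3 was at 9.93 ± 0.546 and 43.3 ± 2.71 FPKM, a difference of -2.02 (limma adjusted p = 8.5e-08). In all, 388 of 11337 genes differed, 81 higher and 307 lower with ivermectin, and of the 41 that differed by at least 1 log2 unit 40 were lower.

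In the cholesterol synthesis list 21 of 23 genes were lower with ivermectin and 2 did not pass (22 when adjusted over the list alone). The median log2 difference was -1.23 (camera adjusted p = 9.52e-45, or 0.00346 with an estimated correlation). The difference was -1.93 for Cyp51, -1.92 for both Msmo1 and Idi1 and -1.52 for Insig1. In the hypoxia list 15 of 17 genes were lower and 2 did not pass (15 lower and 1 higher adjusted over the list alone). Their median difference was -0.81 (camera adjusted p = 6.61e-21, or 0.00346 with an estimated correlation). Slc16a3 differed by -1.58 and Egln1 by -0.81. Of 15 fatty acid synthesis genes 8 were lower and 7 did not pass (10 when adjusted over the list alone). Their median difference was -0.50 (camera adjusted p = 1.07e-10, or 0.0071 with an estimated correlation). Acly differed by -0.90 and Acss2, an acetate-activating enzyme, by -0.73. Of 16 glycolysis genes 14 were lower and 2 did not pass (15 lower and 1 higher when adjusted over the list alone), with a median of -0.49 (camera adjusted p = 1.43e-15; adjusted p = 0.0857 with an estimated correlation). Slc2a1 differed by -1.03 and the aldolase Aldoc by -1.19.

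Of the 13 mitochondrially encoded transcripts 11 were higher with ivermectin and 2 did not pass (12 when adjusted over the list alone). They had a median log2 difference of 0.52 (camera adjusted p = 1.43e-15; adjusted p = 0.174 with an estimated correlation). The difference was 0.80 for mt-Nd3, 0.76 for mt-Co2 and 0.67 for mt-Atp6. The calls of mt-Rnr1 (0.88), mt-Atp8 (0.70) and mt-Co3 (0.63) each ended without ivermectin 2, importazole 2 or importazole 3. That of mt-Rnr1 also ended without ivermectin 3 and that of mt-Co3 also without importazole 1, with adjusted p up to 0.0804, 0.0994 and 0.0851. Srr, which makes D-serine, differed by 0.70. In the amino acid response list 3 of 28 genes were higher with ivermectin, 1 was lower and 24 did not pass (5 and 1 when adjusted over the list alone), with a median of 0.16 (camera adjusted p = 2.09e-05; adjusted p = 0.297 with an estimated correlation). Mthfd2 differed by 0.37 and Ddit4 by -0.98. Gadd45a differed by 0.66 (limma adjusted p = 0.0111), a call that ended without importazole 2 at an adjusted p of 0.0588.

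Of the 39 lists 10 passed, 4 upward and 6 downward, and 3 held with an estimated correlation: cholesterol synthesis, hypoxia-inducible genes and fatty acid synthesis. The number of genes that differed was 214 and 243 without ivermectin 1 and 2, 212, 176 and 226 without importazole 1, 2 and 3, and 231 without both libraries that list Yam1 at 0. The split of higher to lower genes, 81 to 307, was 191 to 274 after quantile normalization, 162 to 279 after median-of-ratios scaling and 228 to 315 after removal of the trend with GC content and length.

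Effects of both compounds were then set beside each other gene by gene. The genes called with both compounds in the same direction numbered 107. Of these 83 rose and 24 fell, against 3.44 and 1.61 expected of independent lists, which leaves out that both comparisons share their vehicle libraries. In 100 simulations of unchanged groups that share a simulated vehicle group, 0 genes were called with both in the same direction. Those groups held no changes, so this cannot show how shared vehicle libraries affect genes that do change. A further 21 genes fell with ivermectin and rose with importazole, against 4.84 expected of independent lists, and 16 of them belong to the cholesterol synthesis list. All 21 differed in the direct comparison, which follows from opposite calls in a single fit and is no separate evidence. Of the 107, 8 differed there. Across genes, the log2 changes correlated with a Pearson r of 0.44 and a Spearman rho of 0.453. Both lay inside the simulated ranges of 0.143 to 0.709 and 0.440 to 0.492. The simulations redrew all libraries, vehicle included, and drew genes independently. Real genes vary together, so the simulated ranges may be too narrow. The share of genes with the same sign, 65.99%, was also inside its simulated range of 65.5% to 67.87%. Their covariance over all genes, 0.0184, lay inside the simulated range of 0.00448 to 0.0237. Without Yam1, which was left out after the data were seen, it was 0.0184 against a range of 0.00825 to 0.0118. The simulations share a vehicle group too, but with genes drawn independently. The 3 real vehicle libraries could not be split, so part of any excess may still come from shared controls whose genes vary together. The 107 became 57 and 69 without vehicle 2 and 3, and 59, 71 and 63 without importazole 1, 2 and 3. The 21 became 13, 12 and 13 without vehicle 1, 2 and 3, and both counts fell to 59 and 11 without the pair of libraries that list Yam1 at 0.

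**Figure D3:**
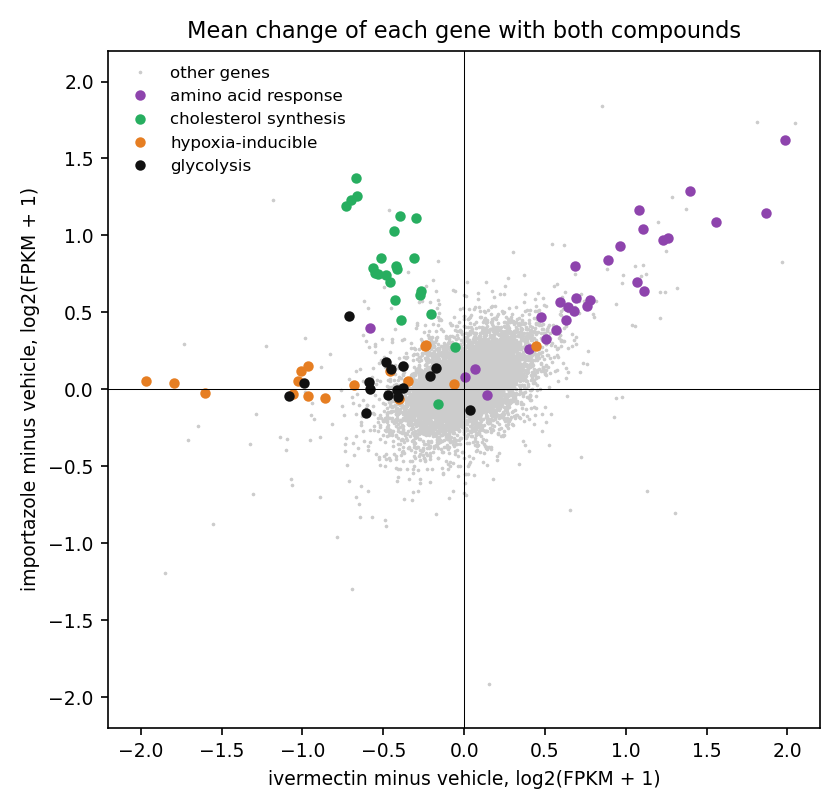
Log2 change of each gene with ivermectin (horizontal axis) and with importazole (vertical axis), both minus vehicle on the log2(FPKM + 1) scale, for 11331 of 11337 genes (6 lie outside the axes). Amino acid response genes lie mostly at upper right, cholesterol synthesis genes mostly at upper left, and hypoxia-inducible and glycolysis genes mostly at left near a vertical value of 0.

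The genes of the transport machinery itself were examined because both compounds act on it. None of the 7 fixed genes, the import receptors Kpnb1, Kpna1, Kpna2, Kpna3, Kpna4 and Kpna6 and the GTPase Ran, passed limma's test in any of the 3 comparisons. Of them 1, 3 and 0 had an unadjusted p under 0.05 for ivermectin, importazole and the direct comparison. Kpnb1, which encodes importin-β (chromosome 11, 97159714 to 97187881, minus strand), was at 76.0 ± 5.25 FPKM in vehicle, 77.2 ± 3.96 with ivermectin and 85.8 ± 4.004 with importazole. In the same order, Kpna1 was at 8.90 ± 0.588, 9.40 ± 0.700 and 9.18 ± 0.634 FPKM, Kpna2 at 64.5 ± 2.81, 69.6 ± 4.68 and 71.5 ± 1.44, and Kpna3 at 6.30 ± 0.353, 7.81 ± 1.46 and 7.72 ± 0.275. Kpna4 was at 13.2 ± 0.679, 14.6 ± 0.650 and 13.7 ± 0.497 FPKM, Kpna6 at 28.1 ± 1.03, 26.7 ± 1.02 and 27.5 ± 1.34, and Ran at 409 ± 81.0, 364 ± 101 and 462 ± 31.9. Of 30 importin and exportin genes 1 rose with each compound, Xpot, the exporter of transfer RNA, from 8.03 ± 0.631 to 13.7 ± 0.442 FPKM with ivermectin and 12.4 ± 0.641 FPKM with importazole (3 and 1 when adjusted over the list alone). The list did not pass with ivermectin (camera adjusted p = 0.188). With importazole it passed narrowly (median log2 change 0.09, camera adjusted p = 0.0401; adjusted p = 0.49 with an estimated correlation), and not without vehicle 1, 2 or 3 or importazole 3 (adjusted p up to 0.113) or under any of 3 other scalings. The nucleoporin list passed upward with both compounds (camera adjusted p = 0.0399 and 0.0167, or 0.139 and 0.129 with an estimated correlation). Its median log2 changes were 0.09 and 0.11, beside 0.014 and 0.041 over all genes tested. With ivermectin 2 of its 30 genes rose and 28 did not pass (5 when adjusted over the list alone), and with importazole 0 of 30 passed limma's test, also 0 when adjusted over the list alone, with 6 higher at an unadjusted p under 0.05. Its call ended without vehicle 1 or ivermectin 1 for ivermectin (adjusted p = 0.165 and 0.118) and without vehicle 1 or importazole 3 for importazole (adjusted p = 0.112 and 0.0599), and without vehicle 2 the median with ivermectin was 0.0542. The call with ivermectin also ended after median-of-ratios scaling (adjusted p = 0.0555), with the trend with GC content and length removed (0.0927) and with a filter at 5 FPKM (0.0688).

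Genes chosen to mark HL-1 cells as heart muscle ranged from abundant to near 0 in all groups. Myh6, a cardiac myosin heavy chain gene, fell from 665 ± 40.5 FPKM to 491 ± 46.7 with ivermectin (limma adjusted p = 0.00854) and 515 ± 8.39 with importazole (0.0321). The first call ended without both libraries that list Yam1 at 0, and the second without vehicle 1, vehicle 2 or importazole 1, 2 or 3, with adjusted p up to 0.137. Nppa, the atrial natriuretic peptide gene, was at 163 ± 13.7, 192 ± 32.3 and 250 ± 11.1 FPKM and rose with importazole (limma adjusted p = 0.0118). This call ended without vehicle 3, importazole 1 or importazole 3 (adjusted p up to 0.0654). Gja1, a gap junction gene, was at 70.5 ± 3.40, 72.6 ± 1.49 and 87.6 ± 6.84 FPKM. Its call with importazole (limma adjusted p = 0.0449) ended under each other scaling and without vehicle 1, 2 or 3, ivermectin 1 or 2 or importazole 2 or 3 (adjusted p up to 0.173). The calcium pump gene Atp2a2, at 777 ± 36.5, 719 ± 34.6 and 698 ± 26.0 FPKM, and the calcium release channel Ryr2, at 9.38 ± 0.989, 9.62 ± 0.168 and 10.8 ± 0.678, did not pass. The potassium channels Kcna5 and Kcnj2 lay below the filter in all libraries.

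Most markers of other cell types lay below the filter and so near 0, with the highest of these at 1.28 FPKM. Markers that passed the filter included the endothelial genes Kdr, at means of 8.23, 7.18 and 8.49 FPKM in vehicle, ivermectin and importazole, and Eng, at 1.13, 1.27 and 1.28, and the macrophage gene Cd68, at 1.01, 1.43 and 1.39. The collagen receptor Ddr2, in the fibroblast list, was at 23.7 ± 1.83 FPKM in vehicle and rose to 36.1 ± 0.912 with ivermectin and 33.7 ± 1.44 with importazole, while Col1a1 in the same list averaged 0.704, 0.805 and 0.849 FPKM. The 5 tested smooth muscle markers, which cardiac cell lines can also express, were lower as a list with both compounds, at median log2 changes of -0.15 and -0.16 (camera adjusted p = 0.0123 and 0.00457; adjusted p = 0.127 and 0.129 with an estimated correlation). By limma 0 of the 5 passed with either compound, 2 and 0 when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05 with each. The call ended with a filter at 5 FPKM and without vehicle 1, 2 or 3 for ivermectin (adjusted p up to 0.0983) and without vehicle 1 or 2 for importazole (up to 0.0691, with a median of -0.0868 without vehicle 1), and for both without the pair of libraries that list Yam1 at 0. Acta2, the most abundant of them, averaged 1215, 1095 and 1078 FPKM.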

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

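The direct comparison and the other groupings of the libraries were planned before the data were examined, and the other 8 tests described here were chosen after the results were seen. All 11 results below were singled out because the effects of ivermectin and importazole differed by the test of the difference itself, at doses of 5 µM and 10 µM that are not matched. The 3 libraries of each group allow 10 ways to split 6 libraries into 2 sets of 3, so a share under 0.1 cannot occur. The true grouping gave 489, 256 and 388 changed genes for ivermectin, importazole and the direct comparison, and the highest other split gave 2, 1 and 3. For gene lists the true grouping gave 21, 19 and 10, and the highest other split 14, 13 and 11. The number of lists past the test in the direct comparison was thus not above what regrouping gave. Every other split mixes both groups unevenly and keeps part of the true contrast. Its lists are therefore not a baseline free of the compounds, and the comparison cannot decide whether the list calls exceed it.

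Cholesterol synthesis genes differed by a median log2 of -1.23 between the compounds. The 21 genes called in opposite directions with both, most of them from this list, also passed the direct comparison. Opposite calls in a single fit lead to that result, so it adds no support. A single odd library could have produced the decrease with ivermectin or the rise with importazole. With each library left out, the median closest to 0 in either comparison with vehicle was -0.399, with ivermectin, and the camera calls held. A trend with GC content and transcript length was also argued against. With that trend removed the median was -0.421 with ivermectin, and the camera call held in both comparisons with vehicle. What underlies the difference stays open, since dose and nuclear import were not tested.

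Hypoxia-inducible genes differed by a median log2 of -0.81 and glycolysis genes by -0.49, both from lower values with ivermectin. The glycolysis call did not hold with an estimated correlation in either comparison (adjusted p = 0.0857 against importazole and 0.0627 against vehicle). It passed the other set test, fry, in both (adjusted p = 1.09e-04 and 1.97e-04). Both libraries that list Yam1 at 0 could have shifted these genes, but without them the medians against vehicle were -0.834 for hypoxia and -0.468 for glycolysis, and removal of the trend with GC content and length left -0.804 and -0.428. Less mRNA of HIF1α could lower its targets, but Hif1a had a log2 change of 0.0759 (SE 0.102). Protein levels, nuclear location and oxygen in the cultures were not measured, so they may still account for the decrease.

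Mitochondrially encoded transcripts differed by a median log2 of 0.52, mostly from lower values with importazole. Against vehicle their median log2 change was -0.45 with importazole and 0.06 with ivermectin, with which 1 of the 13 was called higher and 0 lower. Because they move together between libraries, variation in a single step such as RNA recovery could give the same result. The adjusted p of 0.129 with an estimated correlation, for importazole with vehicle, leaves that open. By fry the list passed in that comparison (adjusted p = 0.0142). The lowest vehicle library lay 0.262 above the highest importazole library in the mean of this list. A trend with GC content and length was argued against by a median of -0.503 with importazole after its removal. A lower mRNA level of the whole respiratory chain was argued against by a median of 0.0176 for nuclear-encoded subunits.

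The other lists singled out for a difference between the compounds are given as values. By fry, fatty acid synthesis (adjusted p = 1.37e-05) and immediate early genes (0.011) passed. The amino acid response (0.0692), endoplasmic reticulum chaperones (0.0596), nuclear-encoded subunits (0.725) and fatty acid oxidation (0.202) did not. By limma 3 of 18 immediate early genes and 1 of 21 chaperones were lower with ivermectin (3 and 2 when adjusted over the list alone). Of 68 nuclear-encoded subunits 1 was higher (0 when adjusted over the list alone). Of 26 fatty acid oxidation genes 1 was higher and 1 lower, also when adjusted over the list alone. Fatty acid synthesis genes differed by a median log2 of -0.50 (camera adjusted p = 1.07e-10, or 0.0071 with an estimated correlation). Amino acid response genes differed by 0.16 (camera adjusted p = 2.09e-05; adjusted p = 0.297 with an estimated correlation). Immediate early genes differed by -0.18 (camera adjusted p = 0.0215; adjusted p = 0.297 with an estimated correlation). Chaperones of the endoplasmic reticulum differed by -0.10 (camera adjusted p = 0.0367; adjusted p = 0.694 with an estimated correlation), a call that ended without ivermectin 1, ivermectin 2 or importazole 2 (adjusted p up to 0.097), with -0.0647 without ivermectin 1. Nuclear-encoded subunits of the respiratory chain differed by 0.04335 (camera adjusted p = 0.0174; adjusted p = 0.914 with an estimated correlation), a call that ended without ivermectin 3 or importazole 2 (up to 0.697), with -0.0323 without ivermectin 3, 0.0844 without ivermectin 1 and 0.0019 without importazole 3. Fatty acid oxidation genes differed by 0.06879 (camera adjusted p = 0.0363; adjusted p = 0.623 with an estimated correlation), a call that ended without ivermectin 3 or importazole 1 (up to 0.149), with 0.0136 without ivermectin 3.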

How the results depend on the processing

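Median-of-ratios scaling and removal of the trend with GC content and length were chosen after the data were seen. So were leaving out Yam1 itself and leaving out both libraries that list Yam1 at 0. The other alternatives were planned. Counts are given for ivermectin, importazole and the direct comparison, then for genes called with both compounds in the same and in opposite directions; the limma counts were 489, 256, 388, 107 and 21. They were 211, 133, 177, 59 and 11 with no filter, where more genes were tested. Stricter thresholds gave 173, 108, 150, 50 and 9 at an adjusted p under 0.01, and 40, 18, 41, 10 and 0 with a log2 change of at least 1, by construction. Fewer libraries left 190, 161, 231, 59 and 11 without both libraries that list Yam1 at 0, 274 for ivermectin in a fit to the 6 libraries compared, and 243 to 398, 127 to 319, 176 to 396, 57 to 89 and 12 to 19 with each library left out. An estimated correlation left 3, 4 and 3 of 21, 19 and 10 lists by camera. With each library left out the numbers were 17 to 22, 13 to 21 and 8 to 11. The other set test, fry, called 21, 17 and 10 lists, with 7, 13 and 1 of them upward. Pseudocounts, a filter at 5 FPKM and each scaling kept gene counts within 1.5 times.

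Of the values of uncalled single genes under an alternative, 10 changed sign, and the cause was not tested. With each library left out, Kpnb1 with ivermectin lay between -0.0221 and 0.0749, Ran between -0.371 and 0.0433 and Ryr2 between -0.0202 and 0.112, and Kpna6 with importazole between -0.065 and 0.00205. With importazole, Kpna1 was at -0.0179 after quantile normalization, -0.00297 after median-of-ratios scaling and -0.0179 with the GC and length trend removed, and Kpna4 at -0.0164 with that trend removed. With ivermectin, Gja1 was at -0.0164 with the trend removed. Signs turned without vehicle 1 for Ryr2, vehicle 3 or ivermectin 2 (-0.00952) for Kpnb1, ivermectin 1 for Ran and importazole 2 for Kpna6. Of 5652 values for single genes under an alternative, 5089 kept direction and side of the threshold, as did 721 of 850 for single lists. Of 198 called results for named genes, 141 kept their call with each library left out. The correlation of both compounds' effects, 0.44, ranged from 0.383 to 0.515 with each library left out.

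With the replicate number as a block the counts of genes were 354, 175 and 257; the cause of the last shift was not tested. The libraries share only a number: their deviations from the group mean correlated, with Yam1 left out, at -0.06783 to 0.1557 over 9 pairs with the same number, and not every library correlated best with its own number. Alternatives planned for read counts (other size factors, other count-based tests) were not run because the files hold FPKM. Depth is unknown, so what it limits could not be tested.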

Other observations

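The genes and lists in this part were chosen after their values were seen, so they are not independent evidence. Apart from the synthetase lists, the genes below show their own changes only, since no wider set of amino acid, hypoxia or lipid genes outside the fixed lists was tested. Aldh18a1 and Pycr1, enzymes of proline synthesis, had log2 changes of 1.12 and 1.06 with ivermectin and of 0.75 and 0.80 with importazole. Pck2, a mitochondrial enzyme induced by ATF4, rose from 17.0 ± 1.23 FPKM to 37.4 ± 1.51 with ivermectin and 29.1 ± 2.12 with importazole, and Slc1a4, a transporter of neutral amino acids, from 5.30 ± 0.206 to 12.6 ± 0.546 and 10.1 ± 0.437. Of 14 cytosolic aminoacyl-tRNA synthetase genes outside the fixed lists 6 rose with each compound and 8 did not pass. Cars rose from 18.5 ± 1.42 FPKM to 37.3 ± 0.820 and 30.4 ± 1.43. As a list they passed with both (camera adjusted p = 1.13e-07 and 3.25e-07; adjusted p = 0.0463 and 0.0532 with an estimated correlation). The 17 mitochondrial synthetase genes did not (camera adjusted p = 0.135 and 0.616). All these values were adjusted over the cytosolic and mitochondrial synthetase lists alone. They are therefore not on the scale of those adjusted over the fixed lists.

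Bnip3l, Higd1a and Ak4, each known to be induced by hypoxia and outside the fixed lists, fell with ivermectin. Bnip3l went from 57.4 ± 3.32 to 29.5 ± 1.61 FPKM, Higd1a from 25.2 ± 0.766 to 14.4 ± 0.472, and Ak4, an adenylate kinase, from 3.42 ± 0.383 to 0.834 ± 0.370. With importazole the same genes were at 54.2 ± 8.99, 25.2 ± 1.93 and 2.94 ± 0.193 FPKM and did not pass. With importazole Pcyt2, of phospholipid synthesis, rose from 67.2 ± 9.59 to 99.7 ± 1.95 FPKM, and the sterol-regulated gene Tmem97, from 71.0 ± 1.09 to 97.6 ± 2.57. The melanocyte antigen gene Mlana rose with importazole from 163 ± 11.0 to 264 ± 12.0 FPKM. Hspb7, a heart-enriched small heat shock protein gene, fell in both, from 174 ± 8.75 to 123 ± 2.38 and 129 ± 9.42 FPKM.

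Vehicle 2 and ivermectin 3, which list Yam1 at 0 while the other 7 libraries hold 24051.3 to 41567.2 FPKM, were also compared over all genes. Their deviations from the group means correlated at 0.3067 with Yam1 and at 0.0123 without it, where the highest value for any other pair from different groups was 0.1557.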
